A study of Mus musculus with 8 samples.

How the data were processed

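RNA sequencing of poly(A) RNA from mouse bone marrow mesenchymal stem cells of the femur was analysed, with 4 libraries from cells given 10 µM ellagic acid (EA) for 48 h and 4 from cells given DMSO. The read counts per gene were made by the authors, whose notes name cutadapt 1.15, HISAT2 2.0.5 and mouse build GRCm39. The read counter, its strand setting and the annotation release are not given in the sources used here. The FPKM values were also computed by the authors, from each count, the gene length and the total of its column. Recomputing 175192 of these values from the counts gave a largest relative deviation of 5.06e-15. Reads of near-identical genes cannot be separated in these counts.

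Counts were analysed in R 4.3.3 with edgeR 4.0.16, with TMM factors, the default count filter by group and a robust quasi-likelihood F test of EA against control without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 over 11777 tested genes were called. Total counts ranged from 14112500 to 17390200 per library, and the biological coefficient of variation was 7.78%. Folds are from the fitted model, and CPM means use TMM scaling, except for summed markers, which use library totals. The SE of a log2 fold change was derived as its size divided by the square root of F. It borrows spread across genes and can be smaller than the libraries of a gene alone would give. Principal components were taken on log2 CPM with a prior count of 2.

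The comparison, the tests, 27 gene lists, 5 lists of cell type markers, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it and with fry, adjusted over 29 lists. Counting members past a threshold adjusted over the list alone changed the counts of higher and lower members of adipocyte genes to 7 and 8, autophagy to 19 and 8, hypoxia to 10 and 10, nuclear oxidative phosphorylation to 10 and 2, and ribosomal proteins to 20 and 1. The names of GO processes and KEGG pathways in the deposited table were tested with 10 to 500 tested genes per term, against genes with any term. Composition measures were compared by exact permutation over 70 assignments. The shares of Fn1, of Postn and of reads in tested genes were not among the planned measures.

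Genes were named by 3 rules. The first took the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of at least 1, a gene symbol that is not provisional and no overlap between groups. The second took up to 2 rising and 2 falling called members of each list by p, or the 2 most expressed members where none was called. The third took up to 3 members by p of the 4 strongest terms per direction. Other genes are marked as chosen after their values were seen. Some genes that these rules select are not reported here.

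The steps were tested on simulated data with 200 changed genes. The edgeR test recovered 49 of 60 genes changed 1.5-fold (81.7%), 69 of 74 changed 2-fold (93.2%) and 65 of 66 changed 4-fold (98.5%), and 13 unchanged genes were called (6.63% of calls). DESeq2 1.42.0 recovered 182 of 200, limma voom 183 and limma on log2(FPKM + 1) 180. A planted list and a planted term were found, with 0 of 20 unchanged lists and 0 other terms past the threshold. The simulated changes were few, went both ways at random and did not shift library composition. In the real data 67.2% of tested genes were called, so these rates do not cover the choice of scaling.

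Alternatives were RLE, upper-quartile and no composition factors, no filter, CPM above 1 in all 8 libraries, DESeq2, limma voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, an adjusted p under 0.01, leaving out mitochondrial genes, a block for replicate number and leaving out each library. List tests with upper-quartile and no composition factors were added after seeing the data. No library was left out of the reported results. Figures were drawn with matplotlib 3.10.9.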

Results

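Gene expression was measured by RNA sequencing in mouse bone marrow mesenchymal stem cells from the femur, the adherent stromal progenitors that can give rise to bone, fat and cartilage cells. Cells were cultured for 48 h with 10 µM ellagic acid (EA), a plant polyphenol, or with the solvent DMSO as control. Each group had 4 libraries of poly(A) RNA, numbered 1 to 4. The labels do not say whether the 4 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. The total count over genes ranged from 14112500 to 17390200 reads per library, with a mean of 15557100 ± 816690 in control and 15730300 ± 1361450 in EA (SD, n = 4 each). Of 21899 protein-coding genes in the table, 17368 had at least 1 read and 11777 had enough reads to be tested.

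The comparison of EA with control asked which transcripts differed after 48 h of exposure. Targets of TGF-beta and BMP signalling, contractile genes and heat shock genes were higher with EA as lists, also with an estimated correlation between genes, and Ccn2, a matricellular growth factor, rose 151-fold. Most tested genes of inflammation, the interferon response, the integrated stress response and cell division were lower, although as lists none of these passed with an estimated correlation (adjusted p = 0.0827 to 0.294, camera). The chemokine gene Cxcl3 had the largest fall of the genes named here, and Nos2, the inducible nitric oxide synthase, was 34.9-fold lower. In all, 3893 genes were higher and 4027 lower at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, TMM scaling), 67.2% of those tested. Among them, 1059 rose by a log2 fold change of 1 or more and 1022 fell by as much. The values of the 4 EA libraries did not overlap those of the 4 control libraries for 7135 genes, 6962 of which were also past the threshold. Chance would separate 2.86% of genes in this way. The first principal component held 84.6% of the variance and parted the groups, at 46.5 to 49.8 in EA and −50.4 to −47.3 in control.

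The division into higher and lower genes depended on how libraries were scaled. TMM factors, which assume that most genes are unchanged or change evenly both ways, were 1.13 to 1.14 in control and 0.878 to 0.885 in EA. With 67.2% of tested genes called, that assumption cannot be taken for granted. The 10 most counted genes of a library took 9.03 ± 0.417% of reads in control and 11.6 ± 0.143% in EA. This difference of 2.55 points is too small to make up the gap between the factors by itself. With library totals alone the counts were 1940 higher and 7196 lower, and with upper-quartile factors 2830 higher and 5338 lower. On log2(FPKM + 1) values limma gave 1924 higher and 7170 lower, and with a pseudocount of 0.1 it gave 1922 higher and 7179 lower. Library totals moved the median log2 fold change of all tested genes by −0.36, FPKM with a pseudocount of 1 by −0.26, FPKM with 0.1 by −0.35 and upper-quartile factors by −0.16. Changes below are relative to TMM scaling.

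**Figure D1:**
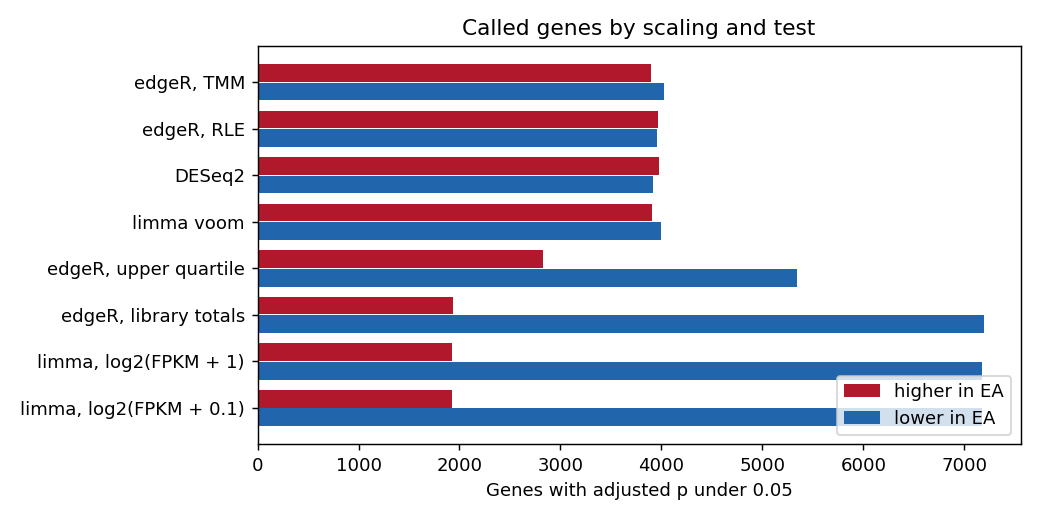
Number of genes with an adjusted p under 0.05 that were higher (red) or lower (blue) in EA than in control, for 8 combinations of scaling and test, on a linear axis that starts at 0. TMM scaling gave 3893 higher and 4027 lower genes, and library totals gave 1940 and 7196.

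The largest rises among well-measured genes, selected by a rule set before the data were examined, included several genes that were close to absent in control. Ccn2 (chromosome 10, 24471340 to 24474581, build GRCm39) went from 2.98 ± 1.09 to 455 ± 54.0 CPM (read counts scaled to a common library size, with SD, n = 4). This was a log2 fold change of 7.24 ± 0.18 (SE derived from the F test). Nfatc2, a calcium-regulated transcription factor, rose from 0.415 ± 0.291 to 60.7 ± 8.71 CPM. Tns1, which encodes the focal adhesion protein tensin 1, rose 58.5-fold from 6.87 ± 1.20 to 401 ± 20.9 CPM. Others were Wfdc3 at 122-fold, Smoc1 at 82.3-fold, Sash3 at 78.3-fold, Lgr6 at 74.6-fold, Rxfp3 at 68.4-fold, Crispld2 at 53.2-fold, the sulfotransferase gene Sult1a1 at 49.4-fold and Ankrd35 at 46.3-fold. Sash3 and Rxfp3 each had 5 reads in the 4 control libraries together, which gives counting intervals of 36.9 to 270-fold for Sash3 and 31.9 to 234-fold for Rxfp3 (95%, exact, counting error only).

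The 12 largest falls held 3 chemokine genes that attract neutrophils. Cxcl3 had 243 reads in control and 3 in EA, a ratio of 63.7 with a counting interval of 21.5 to 311 (95%, exact). Cxcl1 had 265 reads in control and 7 in EA, a ratio of 29.8 with an interval of 14.2 to 74.8. Cxcl5 was 20.7-fold lower, at 25.6 ± 1.88 CPM in control and 1.23 ± 0.619 in EA. Nos2 (chromosome 11, 78811613 to 78851080) was at 216 ± 17.4 CPM in control and 6.15 ± 1.65 in EA, and fell by 5.12 ± 0.12 on the log2 scale. Chac1, a glutathione-degrading enzyme of the amino acid stress response, was 19.4-fold lower, from 171 ± 15.4 CPM. Vnn3 was 16.1-fold lower, Cass4 24.1-fold, the acetylcholine receptor subunit gene Chrnd 20.2-fold and Ciart, a repressor in the circadian clock, 15.1-fold. Usp17la, Usp17lb and Usp17le, near-identical copies of a deubiquitinase gene, were 27.4-fold, 15.3-fold and 16.0-fold lower, but their reads may be shared between copies and their separate values are uncertain.

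**Figure D2:**
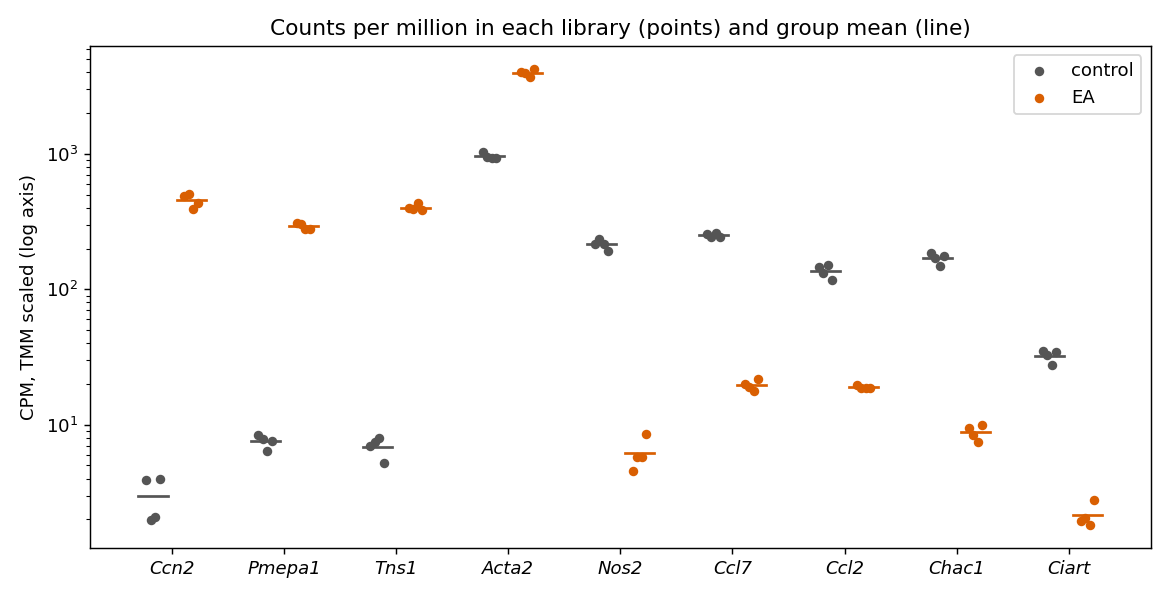
CPM with TMM scaling (log axis) of 4 genes that were higher and 5 that were lower in EA, with a point for each of the 4 libraries per group and a line at the group mean. The groups did not overlap for any of the 9 genes, and Ccn2 had a mean of 2.98 CPM in control and 455 CPM in EA.

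Of 23 tested TGF-beta and BMP target genes, 18 rose and 2 fell, with a median log2 fold change of 2.09 (camera adjusted p = 2.24e-25, and adjusted p = 0.0026 with an estimated correlation). Besides Ccn2, Pmepa1, a feedback inhibitor of TGF-beta signalling, rose 38.7-fold from 7.57 ± 0.839 to 293 ± 16.2 CPM. Of other members chosen after their values were seen, the inhibitory Smad gene Smad7 rose 5.34-fold, Skil 13.4-fold and the BMP-responsive gene Id1 18.3-fold. The falling members were Grem1, a BMP antagonist, at 3.54-fold lower and Ankrd1 at 1.36-fold lower. Among 13 tested contractile and smooth muscle genes, 12 rose and none fell, with a median of 1.60 (camera adjusted p = 1.53e-12, and adjusted p = 0.0126 with an estimated correlation). The smooth muscle actin gene Acta2 rose 4.13-fold, from 965 ± 51.5 to 3987 ± 221 CPM, and the tropomyosin gene Tpm1 rose 3.02-fold, whereas Tagln, chosen after its value was seen, rose from only 0.241 ± 0.266 to 1.69 ± 0.299 CPM.

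Extracellular matrix and cross-linking genes went both ways, with 17 of 25 higher, 8 lower and a median of 1.02 (camera adjusted p = 2.00e-08, but adjusted p = 0.101 with an estimated correlation). The collagen cross-linking enzyme gene Lox rose 7.86-fold, from 405 ± 34.5 to 3184 ± 255 CPM, and the tenascin gene Tnc rose 9.82-fold. Fibrillin 1 (Fbn1) was 2.36-fold lower and Loxl4 1.55-fold lower. Chosen after their values were seen, Postn, which encodes periostin, rose 17.3-fold, Thbs1 8.29-fold and Fn1, the fibronectin gene, 2.16-fold. In shares of all reads, Fn1 went from 1.98 ± 0.0947% to 3.32 ± 0.248% and Postn from 0.121 ± 0.0185% to 1.63 ± 0.121% (exact two-sided permutation p = 0.0286 for each, the smallest that 70 assignments allow, and 0.0429 adjusted over 12 measures). Neither share was a planned measure, so these p-values carry the choice of the genes.

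Of 18 tested osteoblast lineage genes 11 rose and 5 fell, with a median of 0.61 (camera adjusted p = 0.0054, but adjusted p = 0.131 with an estimated correlation). The bone transcription factor gene Dlx5 rose 5.34-fold and Omd, an osteoblast proteoglycan gene, rose 23.4-fold to 18.4 ± 1.03 CPM. Spp1, the osteopontin gene, was 1.86-fold lower at 4962 ± 278 CPM in control and 2671 ± 128 in EA. Of members chosen after their values were seen, the osteoblast master regulator Runx2 rose 2.35-fold and Sp7 8.53-fold, while alkaline phosphatase (Alpl) reached only 2.03 ± 0.363 CPM in EA from 4 reads in all control libraries. Of 9 tested chondrocyte genes 5 rose and 1 fell, with a median of 0.85 (camera adjusted p = 0.0172, but adjusted p = 0.131 with an estimated correlation). Sox9, the transcription factor of cartilage formation, rose 5.45-fold and fibromodulin (Fmod) 5.77-fold, and Chad was 4.11-fold lower from 0.914 ± 0.194 CPM. Adipocyte genes divided into 6 higher and 7 lower of 15 (median −0.28, camera adjusted p = 0.251 against other genes). Without that comparison fry gave an adjusted p of 0.00129 for lower, a test that 26 of 29 lists passed. Fasn and Cd36 rose 1.38-fold and 1.67-fold, and Dgat2, which makes triglycerides, and Cebpd were 4.69-fold and 1.94-fold lower. The adipogenic regulators Pparg and Cebpa had too few reads to be tested.

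Of 18 tested mesenchymal stem and stromal markers 10 rose and 4 fell (median 0.44, camera adjusted p = 0.440). Pdgfrb rose 2.74-fold and Itgav 1.76-fold, and Ly6a, which encodes Sca-1, was 2.82-fold lower beside Grem1. Of 10 tested Wnt targets and antagonists 8 rose and 2 fell, with a median of 1.20 (camera adjusted p = 0.0352, but adjusted p = 0.157 with an estimated correlation). Ccn4 rose 7.18-fold and cyclin D1 (Ccnd1) 1.82-fold. The falling members were the non-canonical ligand gene Wnt5a, 4.49-fold lower, and the antagonist gene Sfrp2, 1.31-fold lower. The antagonist genes Dkk1, Sfrp1 and Sost were among 15 listed genes with too few reads to be tested.

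Of 27 tested genes of G2 and mitosis 26 fell and none rose, with a median of −1.51 (camera adjusted p = 1.53e-15, but adjusted p = 0.185 with an estimated correlation). The spindle assembly factor gene Tpx2 went from 112 ± 7.72 to 38.4 ± 4.84 CPM and was 2.91-fold lower, and Anln, needed for cytokinesis, was 2.51-fold lower. Mki67 and Top2a, chosen after their values were seen, were 2.84-fold and 2.86-fold lower. Of 25 tested S phase genes 20 fell and 4 rose, with a median of −0.92 (camera adjusted p = 0.000416, but adjusted p = 0.294 with an estimated correlation). The helicase subunit gene Mcm7 was 2.52-fold lower and Uhrf1 2.87-fold lower, whereas Rrm1 rose 1.85-fold and Pcna 1.29-fold, although Pcna was no longer past the threshold with library totals or FPKM. Cdkn1a, a cell cycle inhibitor and p53 target, rose 2.04-fold from 140 ± 16.0 to 285 ± 16.5 CPM. The p53 target list as a whole divided into 11 higher, among them Phlda3 at 2.75-fold, and 8 lower of 21, among them Sesn2 at 2.57-fold and the pro-apoptotic gene Bbc3 at 1.77-fold (camera adjusted p = 0.523).

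Of 25 tested genes of the type I interferon response 22 fell and 1 rose, with a median of −1.29 (camera adjusted p = 2.01e-08, but adjusted p = 0.0827 with an estimated correlation). Stat2, a transducer of the interferon signal, was 2.63-fold lower and the interferon-induced gene Xaf1 2.73-fold lower. Ifit1, chosen after its value was seen, was 4.07-fold lower at 39.0 ± 4.83 CPM in control. The rising member, Ifi27, increased 1.19-fold, and this direction reversed with library totals or FPKM. Of 21 tested NF-kB and inflammatory genes 14 fell and 4 rose, with a median of −0.39 (camera adjusted p = 0.000455, but adjusted p = 0.232 with an estimated correlation). Besides Nos2, the chemokine gene Ccl5 was 4.97-fold lower, whereas the prostaglandin synthase gene Ptges rose 2.02-fold and Nfkbia, the inhibitor of NF-kB, 1.40-fold. The rise of Nfkbia was no longer past the threshold with library totals or FPKM. Secreted factors linked to senescence divided into 11 higher and 10 lower of 22 (median 0.35 but mean −0.52, camera adjusted p = 0.722). Vegfa was among the rising members, at 3.59-fold, and the monocyte chemoattractant genes Ccl7 and Ccl2 were 12.8-fold and 7.22-fold lower.

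Of 22 tested genes of the integrated stress response and amino acid synthesis 17 fell and 3 rose, with a median of −0.57 (camera adjusted p = 3.73e-07, but adjusted p = 0.261 with an estimated correlation). Ddit3, which encodes the stress transcription factor CHOP, was 6.71-fold lower from 101 ± 7.17 CPM, beside Chac1. Chosen after their values were seen, Trib3 was 15.0-fold lower and the regulator Atf4 2.04-fold lower. Nupr1 rose 1.33-fold and the amino acid transporter subunit gene Slc3a2 1.21-fold, and with library totals or FPKM Slc3a2 reversed and Nupr1 was no longer past the threshold. Of 15 tested heat shock genes 11 rose and 3 fell, with a median of 0.65 (camera adjusted p = 8.00e-05, and adjusted p = 0.0383 with an estimated correlation). The co-chaperone genes Bag3 and Dnajb1 rose 5.12-fold and 2.78-fold, and Hspd1 and Chordc1 were 1.20-fold and 1.24-fold lower. The unfolded protein response list had 12 higher, among them Dnajc3 and Manf at 1.94-fold and 1.67-fold, and 3 lower, among them Herpud1 and Crebrf at 1.60-fold and 1.68-fold (19 tested, camera adjusted p = 0.523).

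**Figure D3:**
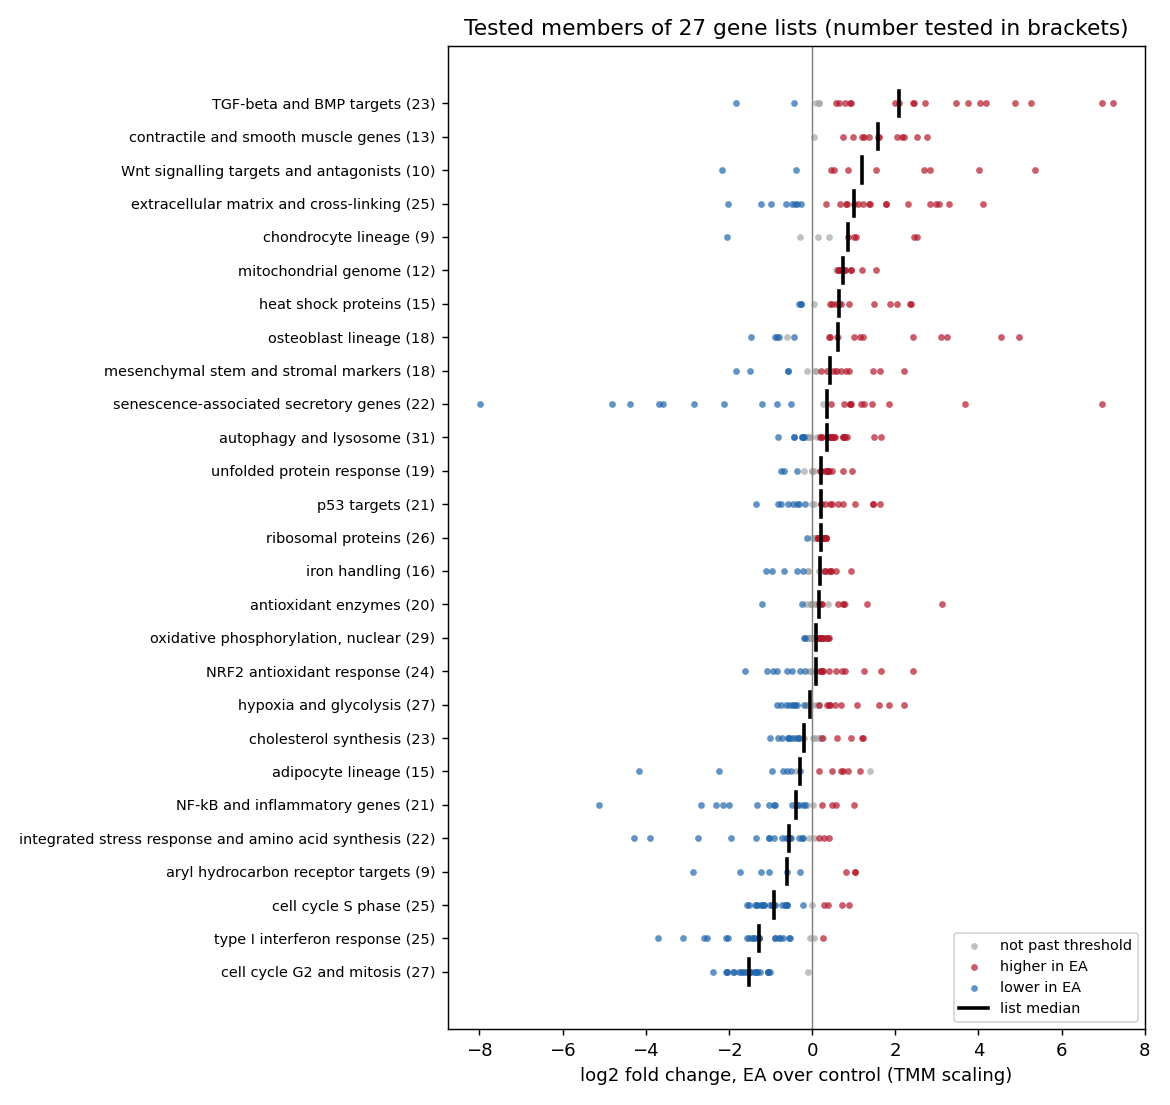
Log2 fold change of EA over control for each tested member of 27 gene lists, with members past the threshold in red (higher) or blue (lower), other members in grey and the list median as a black bar. TGF-beta and BMP targets had the highest median at 2.09 and genes of G2 and mitosis the lowest at −1.51.

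As lists, genes tied to redox balance did not pass with camera. They passed with fry, which tests for a shift in one direction without comparison to other genes. The fry direction was higher for NRF2 targets (adjusted p = 4.94e-05) and antioxidant enzymes (0.000961), and lower for aryl hydrocarbon receptor targets (0.0379). Since 26 of 29 lists passed with fry, this does not set these lists apart. The medians of NRF2 targets and antioxidant enzymes changed sign with library totals, to −0.28 and −0.20. Of 24 tested NRF2 targets 11 rose and 8 fell (median 0.08, camera adjusted p = 0.251). Gclc, the rate-limiting enzyme of glutathione synthesis, rose 5.38-fold from 83.3 ± 8.77 to 449 ± 13.3 CPM and haem oxygenase 1 (Hmox1) 3.13-fold, but the export pump genes Abcc4 and Abcc1 were 2.12-fold and 1.52-fold lower, and Nqo1, a standard NRF2 target chosen after its value was seen, was 1.22-fold lower. Of 20 antioxidant enzyme genes 8 rose and 2 fell (median 0.16, camera adjusted p = 0.251), with metallothionein 1 (Mt1) 8.71-fold and Msrb1 2.49-fold higher and Sod2 and Prdx3, nuclear genes of mitochondrial enzymes, 2.29-fold and 1.18-fold lower. Of 9 aryl hydrocarbon receptor targets 3 rose and 6 fell (median −0.61, camera adjusted p = 0.523). Tiparp and Cyp1b1 rose 1.75-fold and 2.03-fold, Nfe2l2 and Aldh3a1 were 1.52-fold and 2.04-fold lower, and Cyp1a1, the most used readout of that receptor and chosen after its value was seen, was 3.35-fold lower.

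Autophagy and lysosome genes had 19 higher and 7 lower members of 31 (median 0.35, camera adjusted p = 0.104), with Wipi1 and Ctsb rising 2.81-fold and 1.79-fold and Gabarapl1 and Mitf 1.36-fold and 1.76-fold lower. Among 27 hypoxia and glycolysis genes 10 rose and 9 fell (median −0.04 and mean 0.17, camera adjusted p = 0.771). The glucose transporter gene Slc2a1 rose 3.05-fold beside Vegfa, while the glycolytic enzyme genes Tpi1 and Pgk1 were 1.69-fold and 1.47-fold lower. Of 23 cholesterol synthesis genes 5 rose and 10 fell (median −0.19, camera adjusted p = 0.722). Ebp rose 2.29-fold, and Lss was 1.65-fold lower and Pmvk fell by 0.58 on the log2 scale. Of 16 iron handling genes 7 rose and 5 fell (camera adjusted p = 0.957, with a median of 0.18 but a test direction of lower). The ferritin light chain gene Ftl1, which has near-identical copies, rose 1.49-fold and Cp 1.37-fold, and the iron importer genes Slc11a2 and Tfrc were 2.16-fold and 1.59-fold lower. Cp and the adipocyte gene Fasn were no longer past the threshold with library totals or FPKM.

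Transcripts of the mitochondrial genome took 2.61 ± 0.195% of reads in EA and 2.07 ± 0.188% in control (exact two-sided permutation p = 0.0286, adjusted p = 0.0429), and 10 of 12 tested genes rose with none lower (median 0.75, camera adjusted p = 0.0634). Those of mt-Nd4 and mt-Cytb rose 1.72-fold and 1.59-fold. Nuclear genes of oxidative phosphorylation moved little, with 11 of 29 higher, 2 lower and a median of 0.10 (camera adjusted p = 0.864). Ndufv2 and Uqcrc1 rose 1.25-fold and 1.16-fold and both reversed with library totals or FPKM, and Sdhb, among the falling members, was 1.14-fold lower but not past the threshold without control library 1 (log2 fold change −0.14), EA library 1 (−0.19) or EA library 3 (−0.14). Of 26 ribosomal protein genes 19 rose and 1 fell (median 0.21, camera adjusted p = 0.292). Rpl4 and Rps6 each rose 1.26-fold and reversed with library totals or FPKM, and Rps2 was 1.10-fold lower but not past the threshold with RLE factors or without control library 1, 2 or 3 or EA library 1, 2 or 3 (log2 fold change −0.15 to −0.09). The list medians of ribosomal proteins, nuclear oxidative phosphorylation, autophagy, the unfolded protein response, p53 targets, NRF2 targets, antioxidant enzymes, iron handling and senescence-linked secreted factors fell below 0 with library totals, so that no direction is given for these lists.

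Markers of other marrow cells were sparse. Of 20 monocyte and macrophage markers 5 were tested, of which 3 fell and 1 rose (median −0.39, camera adjusted p = 0.124). Cd14 and Cd74 were 3.53-fold and 2.43-fold lower, from 34.0 ± 3.20 and 43.1 ± 1.95 CPM, and Lyz2 rose 1.49-fold from 34.3 ± 4.14 CPM. Chosen after their values were seen, Lgals3 was 1.20-fold lower from 496 ± 26.4 CPM and Cd68 had a log2 fold change of −0.39 ± 0.38 (edgeR adjusted p = 0.377). The summed level of all 20 markers was 692 ± 29.0 CPM in control and 437 ± 21.8 in EA, scaled to library totals, most of it Lgals3, while summed osteoclast markers went from 273 ± 19.1 to 319 ± 5.95 CPM and endothelial markers from 68.0 ± 8.71 to 121 ± 10.8 CPM, most of it Flt1 (exact two-sided permutation p = 0.0286, adjusted p = 0.0429 for each). Library totals by themselves place all genes lower in EA by the shift given above. Of 12 osteoclast markers 4 were tested, of which 2 rose and 1 fell (camera adjusted p = 0.128). Acp5, Calcr, Dcstamp and Tnfrsf11a were among those with too few reads to be tested. Nfatc1 and Itgb3 rose 5.15-fold and 4.79-fold, Mmp9 was 1.89-fold lower, and Ctsk, chosen after its value was seen, was at 122 ± 11.3 CPM in control and 123 ± 5.49 in EA. Of 12 endothelial markers 2 were tested: Flt1 rose 2.38-fold, and Vwf, chosen after its value was seen, was at 1.42 ± 0.510 and 1.11 ± 0.348 CPM. The neutrophil marker S100a8 had a log2 fold change of −0.24 ± 0.41 (edgeR adjusted p = 0.617) and the erythroid marker Alas2 of 0.45 ± 0.34 (edgeR adjusted p = 0.243), both near 1 CPM, and they were the sole tested members of their lists.

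Among 11387 tested genes with a GO process or KEGG pathway, 136 of 2309 terms were over-represented among higher genes and 40 among lower genes (one-sided Fisher exact test, Benjamini-Hochberg over both directions). The Fisher test takes genes as independent, and the terms were not tested under other scalings. Focal adhesion had 98 of 165 genes higher where 54.7 were expected (adjusted p = 7.44e-09, Fisher exact test), among them the adhesion proteins Vcl at 4.71-fold and Actn4 at 3.51-fold. Proteoglycans in cancer had the same counts, with Sdc4 at 6.09-fold, Itpr1 at 4.84-fold and the growth factor gene Fgf2 at 26.3-fold. Angiogenesis had 103 of 177 genes higher where 58.7 were expected, with Glul at 7.61-fold and Fmnl3 at 4.81-fold, and cell adhesion had 140 of 279 where 92.5 were expected, with B4galt1 at 4.09-fold. Also among higher genes were Protein processing in endoplasmic reticulum with 83 of 153 (adjusted p = 1.90e-05, Fisher exact test), Ribosome with 61 of 126 (0.0129) and Lysosome with 52 of 104 (0.0132), although the related lists did not pass camera and their medians were below 0 with library totals.

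Among lower genes, DNA repair had 171 of 336 where 115 were expected (adjusted p = 1.30e-07, Fisher exact test), with Fam111a 3.45-fold lower and the DNA polymerase gene Pole 3.69-fold lower. Cellular response to DNA damage stimulus had 208 of 435 where 149 were expected, with Bcl6 6.69-fold and Gadd45a 5.46-fold lower. Chromosome segregation had 52 of 79 (adjusted p = 4.31e-06, Fisher exact test), with the kinetochore gene Ndc80 6.06-fold, Spag5 2.70-fold and Incenp 2.36-fold lower. Defense response to virus had 68 of 114 where 38.9 were expected. The related lists of S phase, of G2 and mitosis and of the interferon response did not pass with an estimated correlation between genes. The KEGG term Herpes simplex virus 1 infection had 167 of 331 genes lower where 113 were expected. Of its 170 tested genes with zinc-finger names 96 were lower, and of its 161 other tested genes 71 were lower. Among the latter were Nectin2, Traf2 and Ccl2 at 4.10-fold, 2.89-fold and 7.22-fold lower.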

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

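Of the tests in this part, that of unequal depth and that of the scaling of lower genes were chosen only after the result was seen. In 368 groups of 4 values, 30 had a library far from the other 3 by Dixon's test, where chance gives about 18.4. In brackets is the range of the other 3 libraries, in CPM.

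In EA library 4, Bbc3 was at 21.2 (13.3 to 13.9), Fgf2 at 46.6 (60.9 to 62.8), Grem1 at 33.2 (42.4 to 43.0), Itgav at 289.6 (337 to 340.4), Nupr1 at 169.1 (157 to 158), Omd at 16.9 (18.8 to 19.1) and Per2 at 81.1 (74.4 to 75.1), and mitochondrial transcripts took 2.32% of reads (2.68 to 2.73%). In control library 4, Ccl5 was at 16.8 (23.7 to 25.1), Itgav at 204.8 (178 to 181), Lyz2 at 28.1 (36.0 to 37.0) and Per3 at 19.5 (22.8 to 23.2), and 15026 genes were detected (14649 to 14689).

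In control library 1, Acta2 was at 1043 (937 to 942), Nfatc1 at 36.4 (32.7 to 33.1), Runx2 at 70.2 (78.7 to 80.1) and Vwf at 2.18 (1.07 to 1.23). In control library 2, Fgf2 was at 2.89 (1.92 to 2.07) and Wfdc3 at 0.662 (0.160 to 0.229). In control library 3, Gabarapl1 was at 153 (164 to 165), Klf9 at 25.5 (32.0 to 32.6), Sp7 at 3.05 (1.65 to 1.80) and Wnt11 at 0 (0.0533 to 0.0602). In EA library 1, Ccl2 was at 19.7 (18.6 to 18.7). In EA library 2, Rps6 was at 1064 (956 to 970.3), Usp17le at 0.589 (0.0804 to 0.142), Ifit1 at 12.96 (8.45 to 8.52) and Cd68 at 2.06 (0.569 to 0.804). In EA library 3, Fbn1 was at 134 (148 to 150) and Uqcrc1 at 104 (115 to 117).

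The number of called genes was weighed against technical explanations. Of 35 splits of the 8 libraries into 4 and 4, 1 gave as many higher genes, the real one, with 3893 against a highest of 0 in the others, and 1 gave as many lower genes, with 4027 against 0. The other splits mix EA with control libraries, so the group difference enters their residual spread. Their 0 therefore does not show how many genes chance would call. Only the rank of the real split, first of 35, argues against a chance division of these 8 libraries. Chance differences between cultures were not tested, since the libraries of a group may be repeats of 1 culture. Depth is argued against, since totals overlapped (exact permutation p = 0.857). The correlation of fold change with gene length was 0.0256, so the direction of change did not follow length. Because rises and falls cancel in it, this value cannot decide whether longer genes were called more often. Scaling may set part of the direction. With library totals, 49.8% of the 3893 higher genes were still called higher, and 322 of the 3893 were called lower. That 100% of the lower genes were still called lower decides nothing, because library totals move all genes lower. No measure of RNA per cell is available, so the share of higher genes stays open.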

How the results depend on the processing

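List tests with upper-quartile factors and with library totals were chosen after seeing the data. The genes higher in EA numbered 3586 to 3976 and the genes lower in EA 3699 to 4200 with RLE factors, either count filter, DESeq2, limma voom or mitochondrial genes left out, 3338 and 3401 at an adjusted p under 0.01, and 3721 to 4012 and 3794 to 3957 without 1 library. With the replicate block, 3834 were higher and 3960 lower, of which 3804 and 3928 were shared. They were 2830 and 5338 with upper-quartile factors, 1940 and 7196 with library totals, 1924 and 7170 with limma on log2(FPKM + 1) and 1922 and 7179 on log2(FPKM + 0.1). Library totals leave out the TMM correction by construction, and the FPKM settings change the test as well as the scaling. Of 3389 values of 180 named genes, 3325 kept direction and side of the threshold, 30 lost and 2 gained the call, and 32 reversed. With library totals, log2(FPKM + 1) and log2(FPKM + 0.1) in turn the log2 fold change was −0.112, −0.109 and −0.111 for Ifi27, −0.0406, −0.0400 and −0.0410 for Ndufv2, −0.0266, −0.0253 and −0.0253 for Rpl4, −0.0287, −0.0290 and −0.0291 for Rps6, −0.0888, −0.0892 and −0.0894 for Slc3a2, −0.145, −0.140 and −0.145 for Uqcrc1, −0.0131, −0.00607 and −0.00619 for Clock, −0.173, −0.159 and −0.171 for Nr3c1, and −0.353, −0.345 and −0.348 for Ctsk. Ctsk, not past the threshold, was also −0.148 with upper-quartile factors, −0.000961 with CPM above 1 in all libraries, and −0.0411 to 0.0669 without 1 library, negative without control 4 or EA 4 (−0.0133). S100a8 was −0.787 to 0.0181, positive without control 2. Without 1 library, calls were lost for Rps2 (without control 1, 2 or 3 or EA 1, 2 or 3, −0.0884 to −0.146) and Sdhb (control 1, EA 1 or EA 3, −0.137, −0.191 and −0.138), and Cd68 was past the threshold without EA 2 (−0.93). Of 29 lists, 12 passed, 3 with an estimated correlation and 26 with fry, which tests for a shift in one direction without comparison to other genes. Transcripts of the mitochondrial genome passed as a list with library totals (median 0.39), upper-quartile factors (0.60), fry (0.75), or without control 1, control 2, EA 3 or EA 4 (0.72 to 0.84). Except with fry, the direction of a list test is relative to other genes. It can therefore reverse while the list median keeps its sign, as for cholesterol synthesis and hypoxia here. The direction of the list test reversed for cholesterol synthesis with library totals (median −0.554) and without control 3 (−0.0700, range −0.316 to −0.0700), hypoxia with library totals (−0.404), iron handling with fry (0.184), nuclear oxidative phosphorylation with upper-quartile factors (−0.0620), library totals (−0.267) and without control 4 (0.0921, range 0.0618 to 0.138), and ribosomal proteins with library totals (−0.155). The cause of the other changes was not tested. Terms past the same threshold numbered 176, 209 when genes were called at an adjusted p under 0.01, and 186 with the replicate block. The mitochondrial share differed by 0.541 points, or 0.563 by medians. At this depth, genes with few reads had wide counting intervals.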

Other observations

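The 3 sets of tests in this part concern glucocorticoid-responsive genes, circadian clock genes and macrophage markers. For the macrophage markers the tests of the level of the list and of the spread of its members were chosen only after the result was seen. So was the rule on the spread of the clock output genes. All genes named here outside the report were chosen after their values were seen.

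Genes known to respond to glucocorticoid hormones were among the largest rises. Fkbp5 rose 30.2-fold, from 30.7 ± 1.23 to 926.5 ± 35.2 CPM, Errfi1 34.5-fold and Tsc22d3, which encodes GILZ, 17.7-fold. A list of 26 other induced genes was written before it was tested. Its members Mt1, Glul, Nfkbia, Bcl6 and Cebpd were also named in the results by the preset rules, so their values may have been seen. The list is therefore not wholly independent of these data. Of 22 tested, 15 rose, 5 fell and 2 were not called, among the rising ones Sgk1 at 7.13-fold, Klf9 at 7.12-fold and Per1 at 4.85-fold. Their median log2 fold change of 0.82 lay at percentile 100 of 10000 random lists matched on expression, whose 95th percentile was 0.30, and was 0.45 with library totals, which argues against scaling as the whole source. Glucocorticoid activity in the EA cultures is a candidate explanation, and the medium is not given in the sources used here. Against it, Klf15 had 146 reads in control and 6 in EA (ratio 19.1), Bcl6 fell 6.69-fold, Angptl4 3.21-fold, Cebpd 1.94-fold, Ddit4 1.24-fold and Lcn2 1.29-fold, the last not past the threshold with no filter on low counts (log2 fold change −0.37). Of the tested members 5 are also in another list. A different share of stromal cells cannot be told apart, as the stromal marker median was 0.44, 0.538 of the glucocorticoid median. The receptor gene Nr3c1 had a log2 fold change of 0.19 ± 0.06, which reversed with library totals or FPKM.

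Circadian clock genes also moved. Ciart was 15.1-fold lower, Dbp 9.23-fold, Nr1d1 6.48-fold, Nr1d2 3.77-fold and Per3 3.28-fold, whereas Bhlhe41 rose 13.1-fold, Per2 3.32-fold and Arntl 2.91-fold. A different phase of the clock may be present: 3 tested activators and late genes had a median of 0.78 and 6 tested output genes of −0.91. By the rule set beforehand, these opposite signs go with a phase difference. The output genes went both ways, however, with a standard error of 1.01, larger than the size of their median. By a rule added after the result was seen, a phase difference then cannot be told apart from gene-by-gene changes. Clock itself rose 1.27-fold and reversed with library totals or FPKM. Per1 and Klf9 belong to the glucocorticoid list above.

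Macrophage markers differed between the groups, with Cd14 and Cd74 lower and Lyz2 higher, and only 1 called member went against the list median. By the rule set beforehand, so few such members go with a different share of macrophages. With 5 tested markers that rule could not have come out otherwise, so it decides nothing. A different share of macrophages as the source of these changes is argued against by the level of the list as a whole. Scaled to library totals, its 20 markers had a median of 0.106 CPM in control (quartiles 0.0621 and 1.07), whereas the smallest change among the 4 called markers was 6.05 CPM, and macrophages bring their other abundant transcripts too. The 15 markers too low to be tested summed to 2.26 ± 0.723 CPM in control and 2.15 ± 0.155 in EA. Scaling as the whole source is argued against as well, since one factor moves all genes alike. The log2 fold changes of the 5 tested markers had an SD of 0.93, against a mean standard error of 0.142 derived from the F test. The list median of −0.75 with library totals decides nothing here, because library totals move all genes lower. Changes within the stromal cells stay open and were not tested.

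The ligand gene Wnt11 had 3 reads in control and 115 in EA, a ratio of 48.7 (95% exact interval 16.3 to 240).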
